A study of Mus musculus with 74 samples.

How the data were processed

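Genomic DNA of 74 lymphomas of Eµ-myc transgenic mice, which express Myc from an immunoglobulin heavy-chain enhancer and develop B-cell lymphoma, was compared by array CGH with tail DNA of mice of the background strain, on one 2-channel Agilent mouse CGH array per lymphoma. The labels place 50 lymphomas in cluster 1 and 24 in cluster 2 and do not say what defined the clusters. If the clusters were drawn from these same arrays, the comparisons between them are not independent of that choice. The labels do not say that each lymphoma came from a separate mouse, so p-values measure the spread between arrays. No paired analysis was possible because the clusters share no lymphoma numbers.

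Per the file headers, the authors extracted the spot signals with Agilent Feature Extraction 10.1.1.1 on 28 arrays and 10.7.1.1 on 46 arrays. The deposited processed intensity of each channel is background-subtracted, spatially detrended and linearly dye-normalized, per the file headers. The log10 ratio that the authors deposited for each spot is Cy5 over Cy3, per the file headers. The deposited value table holds log2 ratios of Cy5 over Cy3, found by setting each column against that array's scanner values, with a largest difference of 5.29e-06 over 235402 probes and column medians between -0.07 and 0.04. Its own centring stays unknown.

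Per the labels, lymphoma DNA was labelled with Cy3 and tail DNA with Cy5 on every array. The single-channel signals contradict this, as the report shows, so all signed values are given as log2 Cy5/Cy3 and described as higher or lower in Cy5. Under the labels a chromosome higher in Cy5 would be lower in the lymphoma. The counts and tests do not depend on the sign. This differs from the planned ratio of Cy3 over Cy5 by its sign alone.

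Control spots and outlier spots were removed (between 140 and 1609 of 238202 spots per array), repeated spots of a probe were averaged, and each array was centred on its median over autosomal probes, with no loess or quantile step. Of the probes, 233212 had a chromosome position, 11951 of them on chromosome X and 593 on Y. Coordinates are those of the files, mouse build mm8. Between 97.7% and 99.9% of Cy5 spots and between 99.5% and 99.9% of Cy3 spots per array were well above background. The noise of an array was taken as the robust spread of log2 differences between neighbouring probes. The number of arrays limits the precision.

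A chromosome was called when its median was 0.2 or more from 0 and 80% or more of its 1 Mb bins with at least 5 probes lay beyond 0.1 on the same side. Calls were compared by the two-sided Fisher exact test for each autosome and side with 3 or more called arrays, with Benjamini-Hochberg adjustment. Bin medians were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, adjusted p under 0.05). Segments came from penalised least squares (penalty factor 5 times the squared noise times the logarithm of the probe number, at least 5 probes). The altered share is the share of autosomal probes in segments with a mean 0.2 or more from 0. Focal segments are at most 3 Mb long with a mean 0.5 or more from 0. Values per array were compared by a two-sided permutation test of the means with 100000 resamples. Recurrent focal regions were found over all arrays without the clusters, each segment counting for a single region, and those in 4 or more arrays were tested by the Fisher exact test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 did these steps.

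The groups, designs and most alternatives were fixed before the data were examined. The alternatives were normexp on median spot and background signals (offset 50), the authors' value table, centring on the mode, bright probes, loess on intensity (span 0.3), leaving out arrays with noise above 0.3, scan day as a block, other thresholds, penalties, lengths and bin widths, a rank-sum test, array weights and chromosome X. Normexp was planned on mean signals, and median signals were used since the files hold no mean spot signals. It correlated with the values used here with a median r of 0.82 over the arrays (lowest 0.021, and under 0.5 on 11 arrays). Named positions follow a rule fixed in advance: the 1 Mb bin with the smallest p on each chromosome with a called bin, and the 10 most frequent focal regions on each side.

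The files pair no probe with a gene, and the gene table at hand is on another build. The planned comparisons of genes, fixed gene lists, antigen receptor loci and Myc, and the correction for GC content were therefore not run, and regions are named by position alone. Antigen receptor loci could not be left out of the focal segments.

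Both methods were tested on simulated data. For the bin comparison of the clusters, run on 2396 simulated bins, limma recovered 57 of 100 bins shifted by 0.1 and 97 of 100 shifted by 0.2, with 9 false calls. These bins and arrays were drawn independently, without scan-day differences or correlation between neighbouring bins. The number of false calls therefore does not carry over to the real bins. For the segments, on 16202 simulated probes of chromosome 1 with noise of 0.14, all 50 planted segments of 5 probes shifted by 1 were recovered. With noise of 0.45, 0 of 50 were recovered, and all 50 segments of 1000 probes shifted by 0.3 were.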

Results

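Copy number was measured in 74 Eµ-myc lymphomas against tail DNA, 50 in cluster 1 and 24 in cluster 2. Array noise ranged from 0.11 to 0.57 on the log2 scale with a median of 0.16. The arrays were scanned on 8 days, and noise was highest on days 7 and 8, with medians of 0.46 and 0.41. Cluster 1 alone filled days 5, 6 and 8, so 34 of its 50 arrays were scanned on a day without cluster 2. Noise was above 0.3 on 22 arrays, 12 of cluster 1 and 10 of cluster 2. Pairs of arrays correlated with a median r of 0.16 over 212701 autosomal probes, and the highest r was 0.93. The median r was 0.40 for pairs scanned on the same day and 0.14 for pairs scanned on different days. An r under -0.3 was found in 64 of 2701 pairs, and each of these included lymphoma 29, 45 or 48. The lowest was -0.58. After loess on intensity 15 pairs remained under -0.3.

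The first question was which channel carried the copy number changes. Per the labels, lymphoma DNA was in Cy3. In the single-channel signals, each centred per probe within its scan day, all 110 chromosome shifts of 0.2 or more, found in 50 arrays, were larger in Cy5 than in Cy3. The median absolute shift was 0.28 ± 0.16 (SD, 110 shifts) in Cy5 and 0.0037 ± 0.0039 in Cy3. No autosome moved by more than 0.052 in Cy3 on any array. Cy3 did register copy number, since chromosome X moved by more than 0.2 in Cy3 on 36 arrays and by up to 0.82. The signed values below are therefore log2 Cy5/Cy3, and they turn over if the labelled dyes are right.

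**Figure D1:**
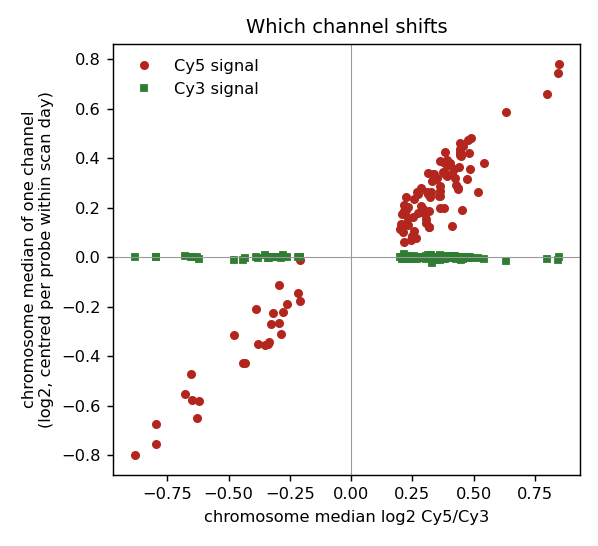
Median log2 shift of each of 110 chromosomes in the Cy5 signal (circles) and in the Cy3 signal (squares), both centred per probe within scan day, against the chromosome's median log2 Cy5/Cy3. The Cy5 shifts have a median absolute size of 0.28, and the Cy3 values have one of 0.0037.

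Whole chromosomes 3 and 15 were called most often, each higher in Cy5 in 18 of 74 arrays. Chromosome 15, which carries Myc, was called in 11 of 24 cluster 2 arrays (45.8%) and in 7 of 50 cluster 1 arrays (14.0%). This difference did not pass the correction (two-sided Fisher exact p = 0.0076, adjusted p = 0.099 over 13 tests). Chromosome 3 was called in 20.8% of cluster 2 and 26.0% of cluster 1. Chromosome 13 was lower in Cy5 in 10 arrays, 9 of cluster 1 and 1 of cluster 2. Chromosome 19 was lower in 7 arrays, 6 of cluster 1 and 1 of cluster 2, and higher in 4. The mean shift was 0.36 ± 0.08 (SD, 18 arrays) for chromosome 3, 0.39 ± 0.14 (SD, 18 arrays) for chromosome 15 and -0.53 ± 0.22 (SD, 10 arrays) for chromosome 13. None of the 13 Fisher exact tests had an adjusted p under 0.05, and 1 had an unadjusted p under 0.05.

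Scan day moved the comparisons of chromosomes 3 and 15. Permuted within scan days, the chromosome 3 difference was -21.7 percentage points in place of -5.17 (permutation p = 0.25, adjusted p = 0.80). The chromosome 15 difference was 14.7 percentage points in place of 31.8 (permutation p = 0.48, adjusted p = 0.80). Chromosome 15 was called in 3 of 6 cluster 2 and 0 of 2 cluster 1 arrays on day 1, and in 0 of 1 and 0 of 3 on day 2. On day 3 it was called in 1 of 3 and 1 of 3, and on day 4 in 2 of 4 and 2 of 6. On day 7 it was called in 5 of 10 and 1 of 2.

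**Figure D2:**
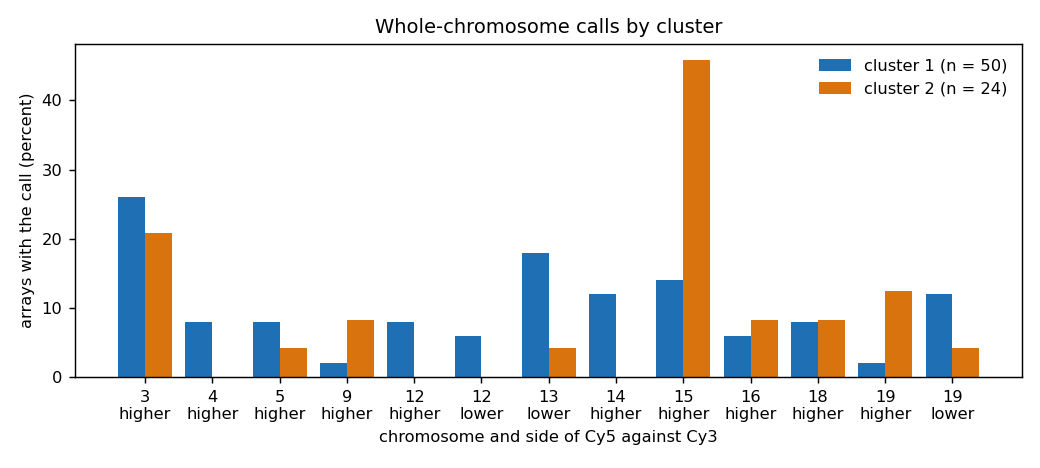
Percent of arrays of cluster 1 (n = 50) and cluster 2 (n = 24) with each whole chromosome called higher or lower in Cy5, for chromosomes called in 3 or more arrays. Chromosome 15 was called in 45.8% of cluster 2 and 14.0% of cluster 1.

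Every lymphoma was then summarised by its number of changed chromosomes. There were 106 calls, 81 higher and 25 lower in Cy5, and 24 arrays had none. Cluster 2 had 1.33 ± 1.20 calls per array (SD, n = 24) and cluster 1 had 1.48 ± 1.63 (SD, n = 50). The clusters did not differ beyond the spread between arrays. Cluster 2 minus cluster 1 was -0.15 calls (permutation p = 0.74), and -0.60 within scan days (permutation p = 0.34).

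In cluster 2, 7.11% ± 7.09 (SD, n = 24) of the autosomal probes lay in altered segments, against 12.8% ± 12.5 (SD, n = 50) in cluster 1. High shares came with and without called chromosomes. Lymphoma 8 had 38.1% with 7 calls, while lymphomas 25 and 24, both of day 6, had 50.5% and 36.3% with 0 calls. Long waves of the ratio along a chromosome would count as altered too. Their part was not tested, and the correction for GC content was not run. The difference between the clusters in altered share, -5.65 percentage points, had a permutation p of 0.042. Segments lower in Cy5 held 1.65% in cluster 2 and 5.64% in cluster 1, a difference of -3.99 points (permutation p = 0.012), and segments higher in Cy5 differed by -1.66 points (permutation p = 0.33). Permuted within scan days, the difference in altered share was -3.39 percentage points with p = 0.32. Within days it was -1.16 points for lower segments (permutation p = 0.55), so that difference did not hold within days. For higher segments, which had not differed over all arrays, it was -2.22 points within days (permutation p = 0.35). For the whole altered share, cluster 2 minus cluster 1 was 1.96 points on day 1, 5.92 on day 2, -4.13 on day 3, -8.96 on day 4 and -3.70 on day 7.

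**Figure D3:**
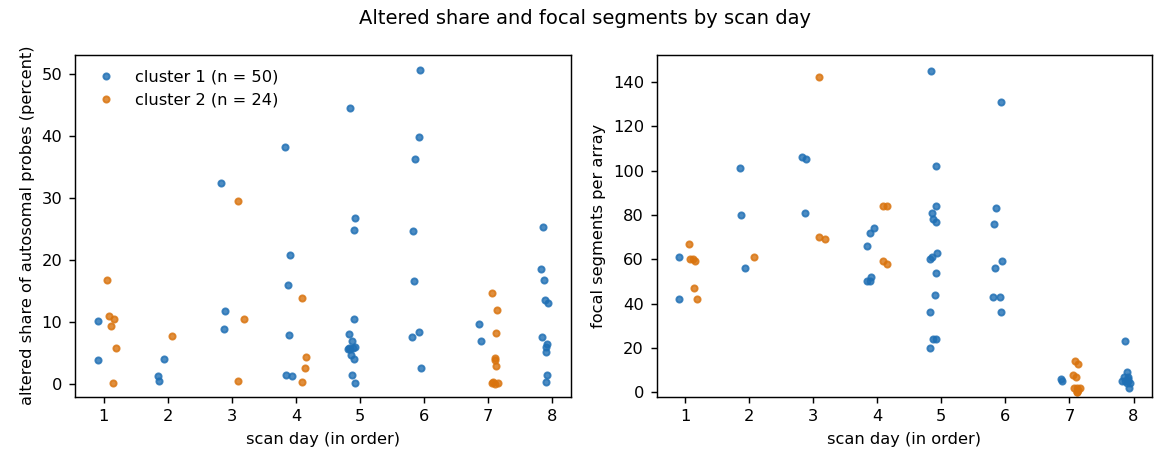
Altered share of autosomal probes in percent (left) and number of focal segments (right) for each array by scan day, with cluster 1 (n = 50) and cluster 2 (n = 24). Arrays with noise above 0.3 had a median of 5 focal segments, against 61 in the others.

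Along the genome, 707 of 2396 bins of 1 Mb differed between the clusters (limma, adjusted p under 0.05), 414 higher and 293 lower in cluster 2. On chromosome 15, 73 of 101 bins were higher and 0 lower in cluster 2. The bin with the smallest p there, from base 18000001 to 19000000 in mm8, was 0.14 ± 0.24 (SD, n = 24) in cluster 2 and -0.12 ± 0.18 (SD, n = 50) in cluster 1, a difference of 0.26 (SE 0.049). The median of the whole chromosome had means of 0.20 in cluster 2 and 0.062 in cluster 1. That difference was 0.13 (permutation p = 0.0026), and 0.084 within scan days (permutation p = 0.29). The negative mean of cluster 1 in the bin therefore does not hold for the chromosome. Long waves of the ratio could move bins too, which was not tested. Chromosome 14 had 40 bins lower in cluster 2, chromosome 9 had 32 higher and chromosome 16 had 36 higher, each with none on the other side. Chromosomes 2, 8 and 11 had called bins on both sides. The smallest p over all bins was on chromosome 7 from base 96000001 to 97000000, at 0.0091 ± 0.056 (SD, n = 24) in cluster 2 and -0.083 ± 0.045 (SD, n = 50) in cluster 1.

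With scan day as a block, 0 bins passed the limma test and 357 had an unadjusted p under 0.05. The median size of the difference over the 707 bins was 0.093 without the block and 0.067 with it, while the median SE rose from 0.028 to 0.036. Within single scan days, 0 bins passed on days 1, 3, 4 and 7. On day 2, where cluster 2 had lymphoma 60 alone, 219 bins passed, and 193 of them were all the bins of chromosome 1, which was called higher in Cy5 in that lymphoma. With arrays centred on the mode, 624 bins passed, 443 of them higher and the others lower in cluster 2.

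**Figure D4:**
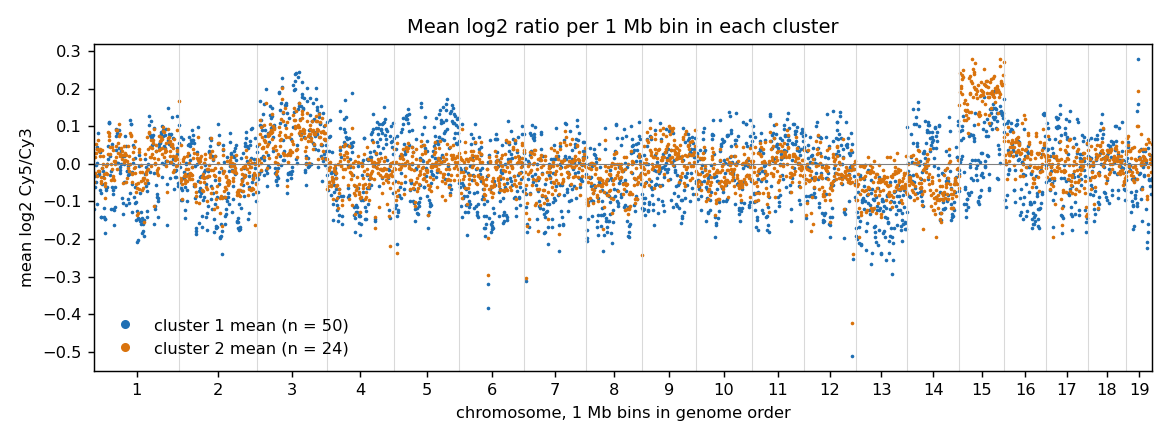
Mean log2 Cy5/Cy3 of each 1 Mb bin in genome order for cluster 1 (n = 50) and cluster 2 (n = 24). On chromosome 15, 73 of 101 bins were higher in cluster 2 by limma without scan day as a block.

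Focal segments numbered 3575 in 72 arrays, with a median length of 63.6 kb. Cluster 2 had 42.1 ± 37.0 per array (SD, n = 24) and cluster 1 had 51.3 ± 36.1 (SD, n = 50), which did not differ beyond the spread between arrays (permutation p = 0.31, and p = 0.81 within scan days). Cluster 2 minus cluster 1 was 4.33 segments on day 1, -18.0 on day 2, -3.67 on day 3, 10.6 on day 4 and -0.60 on day 7. The counts followed noise, with 7 to 145 segments in the 52 arrays with noise up to 0.3 and 0 to 23 in the other 22. The 7 were in lymphoma 17, scanned on day 8 with a noise of 0.30, and the next lowest count was 20. The other 22 arrays were all 12 arrays of day 7 and 10 of the 11 of day 8, so noise and scan day changed together. The minimum of 5 probes was the size of 50.8% of the segments.

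There were 277 focal regions shared by 4 or more arrays, and 35 of them lay on distal chromosome 12, the end that carries the immunoglobulin heavy-chain locus. The tail DNA came from mice of the background strain. Focal regions may therefore be differences between the lymphoma and tail mice rather than changes in the lymphomas, which was not tested. The most frequent region was lower in Cy5 on chromosome 12 from base 113893071 to 113923131. It was found in 51 of 74 arrays, 41 of 50 in cluster 1 and 10 of 24 in cluster 2 (Fisher exact p = 0.00096, adjusted p = 0.17). Permuted within scan days, the permutation p was 0.083. Its segments had a median of 6.5 probes, and noise was above 0.3 on 10 cluster 2 and 12 cluster 1 arrays. Without the noisy arrays no region of chromosome 12 passed the correction. How far noise lowered either count was not tested. Chromosome 2 from base 77680396 to 77822062 was lower in 33 arrays with a median log2 of -2.23, and chromosome 7 from base 37887916 to 37909600 was lower in 30. Chromosome 13 from base 101364751 to 101403828 was lower in 25 arrays, and chromosome 5 from base 94498974 to 95757128 in 19. With loess on intensity these last counts were 38 and 41. With a minimum of 10 probes per segment, the chromosome 12 region was found in 22 arrays, that of chromosome 2 in 33, those of chromosomes 7 and 13 in 0 and that of chromosome 5 in 1. The other 5 of the 10 most frequent lower regions lay on distal chromosome 12, in 19 to 31 arrays when each segment was counted for a single region. Counting any segment over their first base, these 5 were found in 27 to 42 arrays, with 42 for the region from base 114005143.

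Chromosome 11 from base 71035484 to 71072340 was higher in Cy5 in 44 arrays, 29 of cluster 1 and 15 of cluster 2, with a median log2 of 1.93. With dim probes removed it was found in 12 arrays, and with normexp in 2. Counting any segment, 3 of the 277 regions were found in most arrays, which were this one and those of chromosome 12 from bases 113893071 and 114005143. With normexp the latter were found in 36 and 16 arrays, so none of the 3 was then in most of the 74 arrays. Chromosome 4 from base 111570716 to 112091131 was higher in 21 arrays, with normexp in 0, and an overlapping region was lower in 17. Of the 110 regions higher in Cy5, 39 overlapped a region that was lower in other arrays. None of the 277 regions differed between the clusters after correction, and 23 had an unadjusted Fisher exact p under 0.05. Without the noisy arrays 8 regions passed, 6 of them on chromosome 2 and the others on chromosome 13. When those arrays were permuted within scan days, 0 passed. The chromosome 13 regions were higher in Cy5 from bases 76856386 and 77085978. Over all arrays permuted within scan days, their permutation p was 0.0071 and 0.0065 (adjusted p = 0.98 for both). For the chromosome 2 regions it was 0.046 to 0.42.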

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

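The test of the channel and both regroupings within scan days were chosen after the results were seen. The fits without noisy arrays and with scan day as a block and the random groupings were planned, and the limits by which they were judged were set after the results were seen. The tests of the dye normalization and of scan days 5 and 6 were written before.

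A signal stood in a channel that the labels give to tail DNA. All 110 chromosome shifts of 0.2 or more were larger in Cy5 than in Cy3, which is 100% of them. If the authors' dye normalization had moved the shifts from Cy3 to Cy5, unnormalized signals would place them in Cy3. In the unnormalized median signals minus background 100% were larger in Cy5 too, with a median absolute shift of 0.25 in Cy5 and 0.0020 in Cy3. A linear dye normalization scales a whole channel of an array, and centring each channel on its autosomal median removes such a factor. The test could therefore hardly come out otherwise, and no conclusion on the normalization is drawn from it. A candidate explanation is that lymphoma DNA was labelled with Cy5 and the dyes were exchanged in the labels, or that the channels were exchanged in the files. These 2 cannot be separated here, because both give the same values. The design gives no biological group for this pattern, so no biological explanation was tested.

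The clusters differed in 707 of 2396 bins, 414 higher and 293 lower in cluster 2. Of 100 groupings of the arrays, the real one included, 1 gave as many bins, and the highest of the others gave 0, so chance can be excluded for groupings that ignore scan day. When the clusters were regrouped within scan days, the real grouping again gave the most of 100, but the highest of the others gave 664 and their median was 53. The arrangement of the clusters over scan days thus gives many bins by itself. With scan day as a block 357 bins had an unadjusted p under 0.05, and 4 of 100 groupings within days, the real one included, gave as many. The highest of the others gave 607. Noisy arrays are argued against as the whole source, since 379 of the 707 bins were still called without them. If scan day were the whole source, the real grouping would stand out from groupings within days only by chance. It ranked 1 of 100 without the block and 4 of 100 by unadjusted counts with it. These ranks argue against scan day alone as the source of the number of bins. How much of the difference scan day gives stays open. With scan day as a block 72.1% of the median difference was kept (0.093 before, 0.067 after), and 700 of the 707 bins kept their direction. These bins were picked for their difference in the same arrays, so part of this agreement is built in. Without the block, the other groupings within scan days gave median differences over these bins with a median of 0.060 and a highest of 0.085. These sizes compare with 0.093, and none were computed with the block to set against 0.067. Since the bins were picked in the same arrays, the share kept does not show how much of the difference is free of scan day. The limma calls ended because the difference shrank while its median SE rose from 0.028 to 0.036. Within cluster 1, 565 bins differed between scan days, so arrays of 1 cluster did differ by day. Cluster 1 arrays from days with and without cluster 2 differed in 10 bins, 2 of them among the 707. The part kept with the block comes from days with both clusters, which hold 16 cluster 1 and 24 cluster 2 arrays. With the block 0 bins passed over all arrays and 5 on those days alone. The fits with the block therefore do not settle which bins differ between the clusters apart from scan day. A copy number difference between the clusters, which is the biological explanation the design names, stays among the open ones.

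Cluster 2 had a smaller share of the autosomal probes in altered segments (difference of -5.65 percentage points, permutation p = 0.042). Scan days 5 and 6 hold cluster 1 alone, and the altered share was highest on day 6, with a mean of 23.3%. Without the arrays of both days the difference was -3.63 percentage points (permutation p = 0.14, 51 arrays). Most of its size was kept, yet the remainder was within the spread between arrays, so shifts of those days and a difference between the clusters cannot be told apart. A difference in the lymphomas themselves stays open.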

How the results depend on the processing

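Most alternatives were set before the data were seen. Single days, days with both clusters, 2 joined choices and the 10-probe minimum came after. Results that answer the comparisons were kept in 53 of 81 repeats. Kept means direction and threshold side for a difference, and a change within 1.5 times for a count. Most of the 53 belong to results that had not passed the threshold. Value-table repeats use the same data. Bins past the threshold, 707 of 2396 as reported, were 369 with normexp, 412 without noisy arrays and 355 at an adjusted p under 0.01. Such bins numbered 1230 by the Wilcoxon test, 1613 with array weights and 116 of 502 with 5 Mb bins, where fewer bins were tested. They were 0 in limma with scan day as a block (357 at an unadjusted p under 0.05), 29 on days with both clusters, 5 there with the block, 0 without noisy arrays with the block (218 unadjusted), 219 within day 2, which rests on 1 cluster 2 array assumed to vary like the others and has 193 of them on chromosome 1, and 0 within days 1, 3, 4 and 7 (96, 2, 197 and 255 unadjusted). The difference in altered share, -5.65 percentage points, was -4.72 without noisy arrays, -3.39 within scan days, -3.31 at a threshold of 0.3 (-10.5 at 0.15, permutation p = 0.0075), -5.18 with the penalty doubled, -3.85 on days with both clusters and -3.30 without noisy arrays within days, with permutation p from 0.054 to 0.43 for the 6 that missed the threshold. The difference in changed chromosomes reversed to 0.17 without noisy arrays. That in focal segments reversed to 3.37 without noisy arrays, 1.52 within days and 2.10 with both. Recurrent regions past the threshold were 1 with normexp, 3 with loess, 8 without noisy arrays and 0 without noisy arrays within days. Among named items, 2 bin differences reversed without noisy arrays with the block, to -0.0075 on chromosome 13 and -0.017 on chromosome 18. The chromosome 3 difference reversed to 0.38 percentage points without noisy arrays, and that of chromosome 13 to 1.63 without noisy arrays within days. On distal chromosome 12, with any segment counted, 5 of the 6 named lower regions fell from between 27 and 42 arrays to between 14 and 17 with normexp, and the most frequent from 51 to 36. The chromosome 13 region fell from 25 arrays to 8 with the penalty doubled. Over the repeats of named items that did not reverse, bins were weaker in 83, focal regions were weaker in 46 and stronger in 2, and the rest, with 42 for chromosomes, were the same. Unless stated, the cause was not tested. Noise limits the focal segments, since 0 of 50 segments of 5 probes were recovered at a simulated noise of 0.45. Genes, gene lists, antigen receptor loci with Myc and the GC correction were not run.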

Other observations

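The tests of chromosomes 3 and 15 and of chromosome 2 were chosen after the results were seen, as were the blocks on chromosomes 12 and 6.

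Chromosomes 3 and 15 were higher in Cy5 in the same arrays. Both were called in 11 arrays, chromosome 3 alone in 7, chromosome 15 alone in 7 and neither in 49 (Fisher exact p = 0.00011, adjusted p = 0.0084 over 76 pairs). The pair was seen in 6 arrays of cluster 1 (Fisher exact p = 0.00065) and in 5 arrays of cluster 2 (Fisher exact p = 0.011). Permuted within clusters and within counts of other changed chromosomes, the p was 6.00e-05, with a mean of 4.70 joint arrays by chance. Permuted within clusters and scan days, the permutation p was 0.00013, with a mean of 4.95 joint arrays by chance. The calls used ratios that were not centred within scan days. Centred per probe within scan day, the Cy5 shifts of both chromosomes stayed at 0.2 or more in lymphomas 33, 65 and 67. In the other joint arrays chromosome 3, chromosome 15 or both were under 0.2. The lowest were 0.10 and 0.078, in lymphoma 63. Centring on the median of a day can also take out part of a change that many of its arrays share. On day 7, that of lymphoma 63, chromosome 15 was called in 6 of 12 arrays. The centred values therefore do not show that a joint call was wrong. Chromosomes 3 and 15 may be changed together more often than their frequencies give, which stays a hypothesis from the same data. Chromosomes 3 and 5 were both higher in 5 arrays (Fisher exact adjusted p = 0.020), and chromosomes 12 and 13 were both lower in 3 (Fisher exact adjusted p = 0.047). Centred within scan day, chromosome 3 was at 0.10 to 0.18 in Cy5 in those 5 arrays, and chromosome 5 at 0.12 to 0.74. In those 3, chromosome 13 was at -0.011 in lymphoma 10, -0.35 in lymphoma 8 and -0.47 in lymphoma 13. On day 8, that of lymphomas 10 and 13, chromosome 13 was called in 5 of 11 arrays, so the centring may have taken out part of it.

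Without the noisy arrays, 6 regions of chromosome 2 between bases 56999462 and 108083112 in mm8 were more often higher in Cy5 in cluster 2. Permuted within scan days, none of these differences passed (0 regions). Any of them was found in 12 of 52 arrays, 8 of cluster 2 and 4 of cluster 1. These 4 were among the 14 cluster 1 arrays from days with both clusters, against 0 of 24 from other days. In 6 arrays 5 or more regions were found, 6 of 14 in cluster 2 and 0 of 38 in cluster 1. An array with a region carried a median of 3 of the others, against 1 when the arrays of each region were shuffled within clusters (permutation p = 0.0001, the smallest that 10000 resamples can give). Shuffled within both clusters and scan days, the permutation p was 0.00020. The regions may be carried together. A source in the mice was not tested. They were chosen for their difference between clusters, so that difference is no independent evidence.

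Distal chromosome 12 from base 113722237 to 116319126 was below 0 in 66 of 74 arrays. Its mean was -0.32 ± 0.37 (SD, n = 24) in cluster 2 and -0.42 ± 0.45 (SD, n = 50) in cluster 1 (permutation p = 0.35). Cluster 2 minus cluster 1 was 0.10, and 0.23 within scan days (permutation p = 0.14). Chromosome 6 from base 68669993 to 69568819, with 61 probes, had means of -0.36 ± 0.50 (SD, n = 24) and -0.37 ± 0.77 (SD, n = 50) (permutation p = 0.99). Here cluster 2 minus cluster 1 was 0.0022, and 0.27 within scan days (permutation p = 0.32). These ends and stretches were picked from the data, and they were not matched to genes.

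On the sex chromosomes, 12 arrays had X lower and Y higher in Cy5 by 0.5 or more, 23 had X higher and Y lower, and 32 had neither. In 3 arrays X was near 0 and Y was lower, all in cluster 2: lymphoma 58 with Y at -1.08, lymphoma 59 at -1.49 and lymphoma 72 at -1.84. Lymphoma 1 had X at -0.95 and Y near 0. In the other 3 arrays X was within 0.5 of 0 and Y was higher, at 1.55 in lymphoma 2 and 0.62 in lymphoma 50 of cluster 1 and at 0.56 in lymphoma 61 of cluster 2.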
